A study of Mus musculus with 13 samples.

How the data were processed

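Gene expression was measured on single-colour microarrays in eosinophils sorted from the lamina propria of the mouse small intestine. Per the labels' protocols, RNA was extracted with a column kit for small samples, and biotinylated cDNA was made from 2 ng of total RNA per array with a whole-transcript amplification system. The arrays came as 2 tables of different array designs. The first held 5 arrays of mCherry+ and 5 of mCherry- eosinophils from Clec4a4-mCherry reporter mice, with 35556 probe sets. The second held 1 array each of wild-type (WT) Clec4a4+ eosinophils, WT Clec4a4- eosinophils and Clec4a4- eosinophils labelled as Ahr knockout (KO), with 28360 probe sets. The labels call the reporter arrays biological replicates without saying whether each came from 1 mouse or from a pool.

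The deposited values are on a log2 scale, and RMA made them, per the submitters' processing notes, which give no version or settings. RMA as a method subtracts background, equalizes the distribution of all arrays of a table and combines the probes of a probe set, so a change that shifted most genes alike could not be seen in such values. Array medians lay between 5.18 and 5.27 in the first table and between 4.73 and 4.75 in the second. The 2 tables were normalized apart, and no level was tested across them. Each table was deposited in 2 forms, which held equal values within 1e-06, so the form used changed nothing. The number of arrays, not a read depth, limits the precision. Genome coordinates were not used, since the build is not given in the sources used here.

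Probe sets were named through the gene ID or transcript accession that the deposited tables pair with each probe set, matched to a RefSeq gene table (assembly GRCm38.p6, used for names only), and otherwise through the symbol in the file. Of the reporter probe sets, 22106 were named by gene ID, 1934 by accession and 410 by the file's symbol, and 11106 stayed without a name. For the single arrays these numbers were 24119, 1964, 1117 and 1160. No probe set had several names. For a gene with several probe sets the one with the highest mean over the table's arrays was kept, which left 21369 and 24903 genes.

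In the reporter comparison, genes above the array's median over all probe sets on at least 5 of the 10 arrays were tested, 11631 in all. limma (lmFit and eBayes) compared mCherry+ with mCherry- eosinophils without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p, which is two-sided. Fold changes are given on the log2 scale with the moderated standard error of limma. A total of 29 gene lists, of pathways and of markers of other cell types, were tested as sets with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists with at least 3 measured genes. The mast cell and basophil list had 2 measured genes and was not tested. For the single arrays no test was possible. There a gene was counted where the log2 difference was at least 1 in size and the higher array lay above its median, and a list's median difference was placed among 10000 random lists of the same size matched on mean level. Genes called at least 2-fold higher or lower in mCherry+ eosinophils were followed in the single-array pairs in the same way. These lists come from other arrays than the pairs and share no control with them. Both pairs use the same WT Clec4a4- array, so their differences are not independent of each other.

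The reporter arrays carry replicate numbers shared by both groups. Arrays of the same number deviated together from their group means, with correlations across genes of 0.74, 0.17, 0.17, 0.60 and 0.24 for numbers 1 to 5, and each was above 0.1. The numbers were therefore taken to pair the arrays, and the value from a fit with the replicate number as a block is printed where it changed the call of a list or of a gene named below, or moved a count by over 1.5 times; for list members the counts with the block are given where they differ. Some arrays of different numbers correlated about as much, at 0.30 for mCherry+ replicate 4 with mCherry- replicate 5. The correlation was 0.17 for mCherry+ replicate 5 with mCherry- replicate 4, and 0.13 for mCherry+ replicate 2 with mCherry- replicate 3. The pairing is thus clear for numbers 1 and 4, and less so for 2, 3 and 5. That the numbers mark shared mice or sorting days is not stated in the labels.

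The groups, tests, gene lists, thresholds, alternatives and the rule for named genes were chosen before the data were examined. That rule names Clec4a4 and Ahr, the 12 higher and 12 lower genes with the largest fold change past the threshold in the reporter comparison, up to 4 called members per list, and in each single-array pair the 10 higher and 10 lower genes with the largest difference plus up to 4 members per list that differed at least 2-fold. Predicted genes, small RNAs, olfactory and vomeronasal genes and antigen receptor segments were left out of the names. Xist, Ddx3y and the members of other cell types' lists whose levels are given without passing the rule were chosen after their values were seen, as were the uncalled genes named among the eosinophil, chemokine and AHR target genes. Alternatives covered the block, the filter, renormalization, centring, the prior of limma, array weights, probe set averaging, the threshold, the form of the deposited table and leaving out each array. Leaving out the arrays numbered 1 or those numbered 4 was added after the data were seen. The closing section gives their effect.

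The steps were tested on simulated data. With 200 of 11631 genes changed on values drawn with the spread of the reporter arrays, the limma fit recovered 51.0% of genes changed by 1 and 89.0% of genes changed by 2 on the log2 scale, with 1 false call, and with the block 69.0% and 95.0%, with 11 false calls. In the set test 20 of 20 lists shifted by 0.7 were called and 0 of 20 unchanged lists. These simulated lists held genes drawn at random, with residual noise independent between genes. They do not show how often lists of genes that vary together are called falsely. For the percentile against random lists 5000 genes were simulated apart. There 39 of 40 lists shifted by 0.5 lay above the central 95% of random lists, and 4 of 40 unchanged lists lay outside it. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.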

Results

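Eosinophils, granulocytes that reside in large numbers in the intestinal mucosa, were sorted from the small intestinal lamina propria of mice by whether they expressed Clec4a4, a C-type lectin receptor with an inhibitory signalling motif. In reporter mice mCherry stands for Clec4a4. There 5 arrays of mCherry+ and 5 of mCherry- eosinophils were compared to find the genes that distinguish the subsets. A further 3 arrays, 1 per group, held WT Clec4a4+ eosinophils, WT Clec4a4- eosinophils and Clec4a4- eosinophils labelled as lacking the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor, to find which genes depend on it. All values are RMA values on the log2 scale. Correlations between arrays of one group across the 11631 tested genes ran from 0.842 to 0.955 in mCherry+ and from 0.810 to 0.954 in mCherry- eosinophils. The first principal component, with 40.4% of the variance, set both arrays numbered 1 (-46.5 each) apart from both arrays numbered 4 (34.7 and 44.8), and the second, with 15.7%, separated mCherry+ from mCherry- eosinophils. The arrays numbered 1 alone had Xist signal (9.90 in mCherry+ and 10.36 in mCherry-, against 3.56 to 3.93 on the other arrays).

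The question of the first comparison was which genes mark Clec4a4-expressing eosinophils. The mCherry+ cells had a higher level of Dpep2, a membrane dipeptidase that cleaves leukotriene D4 (log2 fold change 2.83 ± 0.36, SE, n = 5 per group, limma adjusted p = 0.00518). Also higher were the AHR target Cyp1b1, a cytochrome P450 (2.81 ± 0.26, adjusted p = 0.000856), Cd22, a sialic acid-binding inhibitory receptor (2.58 ± 0.25), and the scavenger receptor gene Fcrls (2.36 ± 0.30). Lower in these cells were the calprotectin subunits S100a8 and S100a9, which fell by 5.27 ± 0.51 and 5.03 ± 0.58 (limma adjusted p = 0.000869 and 0.00323). Also lower were the complement C5a receptor C5ar1 (-3.69 ± 0.19, adjusted p = 1.19e-05), the cytokine Osm (-3.18 ± 0.22) and the pattern recognition lectin Clec4e (-3.03 ± 0.20). In total 119 genes differed at a limma adjusted p under 0.05, 51 higher and 68 lower in mCherry+ cells, and 88 of them by at least 2-fold, 38 higher and 50 lower. With the replicate number as a block the fit called 403 genes, 232 higher and 171 lower, of which 155 differed at least 2-fold (75 higher, 80 lower), and 51 of the higher and 67 of the lower genes were called in both fits. Sec14l1 (-0.95) lost its call with the block (adjusted p = 0.0597). Leaving out mCherry+ replicate 1, 2, 3 or 5 reduced the count of 119 to 66, 49, 45 or 46. Leaving out mCherry- replicate 2, 3 or 5 reduced it to 60, 57 or 59, and leaving out both arrays numbered 1 to 52 (166 with the block). For the 88 genes these counts were 56, 42, 41 or 38, then 49, 51 or 51, and 44 (106 with the block).

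Clec4a4 itself lay at 9.18 ± 0.62 (SD, n = 5) in mCherry+ and 7.52 ± 0.62 in mCherry- eosinophils, a difference of 1.66 ± 0.35 (SE) that was positive in 5 of 5 numbered pairs. Its limma adjusted p was 0.0542 without and 0.00243 with the replicate block, and ran up to 0.15 over the alternatives. It was called under 7 of 23 alternatives, the block and leaving out mCherry+ replicate 4 (difference 1.88) among them. The mean Clec4a4 level of mCherry- cells was above the array medians of 5.18 to 5.27, so these cells were not free of Clec4a4 signal. Ahr was at 11.10 ± 0.44 and 10.09 ± 0.64, a difference of 1.00 ± 0.31 that was positive in 5 of 5 pairs, with an adjusted p of 0.232 without and 0.0074 with the block and up to 0.438 over the alternatives. Further named genes that rose in mCherry+ eosinophils were Ly86, a partner of the toll-like receptor homologue RP105 (2.09 ± 0.35), the polysialyltransferase St8sia4 (1.75 ± 0.24), the organic anion transporter Slco4a1 (1.71 ± 0.30), the transcription factor Egr2 (1.66 ± 0.32), Cep85l (1.65 ± 0.29), the thrombin receptor F2rl3 (1.59 ± 0.26), the mevalonate pathway kinase Pmvk (1.54 ± 0.22) and the lectin Clec4b2 (1.52 ± 0.25). Those that fell were the eosinophil ribonuclease Ear6 (-2.87 ± 0.33), the itaconate-producing enzyme Acod1 (-2.77 ± 0.35), Rassf4 (-2.73 ± 0.23), the lectins Clec4a2 (-2.61 ± 0.39) and Clec7a (-2.38 ± 0.36), and the cytokines Il6 (-2.44 ± 0.45) and Tnf (-2.40 ± 0.42). Each of these genes moved the same way in 5 of 5 pairs. In mCherry+ cells C5ar1 (5.01), Osm (5.05), Ear6 (5.02), Clec7a (5.09), Rassf4 (4.54), Clec4a2 (4.29), Il6 (4.24), Clec12a (4.69), Clec4n (4.84), Tnfsf14 (4.64) and Ear1 (5.11) lay below the array medians of 5.18 to 5.27, so that the sizes of their decreases are not exact. Of the 39 called genes named by the rule, 24 kept their call whichever single array was left out. Of these Cyp51, Pmvk and Clec7a lost it without both arrays numbered 1 (adjusted p = 0.0652, 0.0511 and 0.0511). The other 15 (Ly86, Slco4a1, Egr2, Cep85l, F2rl3, Clec4b2, Il6, Tnf, Ear1, Clec12a, Tnfsf14, Ctsd, Ptgs2, Hmgcs1 and Cd68) lost it without at least 1 array, up to an adjusted p of 0.133 for Clec12a, and the number lost ran from 1 gene without mCherry- replicate 4 to 14 genes without mCherry+ replicate 3.

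**Figure D1:**
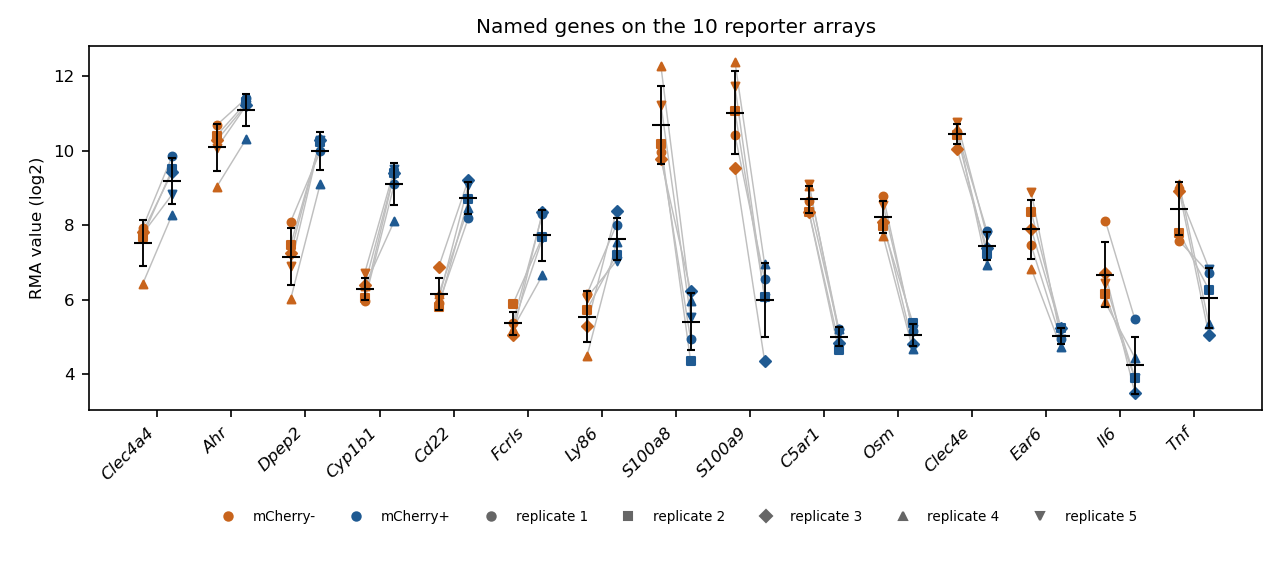
RMA values (log2, vertical axis) of 15 named genes on the 5 mCherry- (orange) and 5 mCherry+ (blue) arrays. Symbols mark the replicate number, grey lines join arrays of the same number, and black bars show the mean and SD of each group; S100a8 lay between 9.77 and 12.27 on the mCherry- arrays and between 4.36 and 6.25 on the mCherry+ arrays.

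Genes of cholesterol synthesis rose in mCherry+ eosinophils. Of 19 measured members of the list, 9 were called higher and 0 lower, 15 when adjusted over the list alone, and 14 with the replicate block. The median log2 fold change was 1.05, with a positive list mean in 5 of 5 pairs. Named members were the methylsterol oxidase Msmo1 (1.44 ± 0.19), the lanosterol demethylase Cyp51 (1.19 ± 0.19), the HMG-CoA synthase Hmgcs1 (1.07 ± 0.18) and the sterol desaturase Sc5d (1.05 ± 0.13). The list was called by limma's camera (adjusted p = 2.37e-23, and 0.0449 with an estimated correlation). With the replicate block and an estimated correlation it was not called (adjusted p = 0.162), and without both arrays numbered 1 the number of called members was 2, or 8 with the block. The erythroid and platelet list had a median of 1.33 over 6 measured members, of which 0 were called, or 2 when adjusted over the list alone, with Hba-a2 at 1.57 ± 0.52 and Ppbp at 1.17 ± 0.52 but Gp9 at 0.02 ± 0.17 and Slc4a1 at -0.13 ± 0.11. It passed camera at an adjusted p of 0.0321, but not with an estimated correlation (adjusted p = 0.132) or without the arrays numbered 1 (adjusted p = 0.0907).

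C-type lectin receptors fell as a list in mCherry+ eosinophils, while Clec4b2 rose. Of 10 measured members 5 were called lower and 1 higher, 8 and 2 when adjusted over the list alone, and 7 and 2 with the replicate block. The lower members were Clec4e, Clec4a2, Clec7a, Clec4n and Clec12a (-2.12 ± 0.43) and the higher one was Clec4b2. The second higher member over the list alone and with the block was Clec4a4. The median over the list was -2.22 (camera adjusted p = 1.5e-07, and 0.0449 with an estimated correlation). That p was 0.0506 with the block and an estimated correlation, and without the arrays numbered 1 the called members numbered 2 lower and 0 higher. The neutrophil markers S100a8 and S100a9 were lower in the same cells, and Lcn2, Stfa2l1, Csf3r (9.65 and 8.68) and Cd14 (10.25 and 9.67) were high on mCherry- replicates 4 and 5. The lectin list mean differed by -1.23, -1.10 and -1.26 in pairs 1 to 3 and by -1.56 and -1.54 in pairs 4 and 5.

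Lists of NF-kB genes and of cytokines fell in mCherry+ eosinophils, as did the neutrophil markers S100a8 and S100a9. Of 18 measured genes of NF-kB feedback and activation, 8 were called lower and 0 higher (13 lower and 1 higher when adjusted over the list alone, 12 and 0 with the block). Among the lower were the inhibitor Nfkbia (-1.51 ± 0.22), the adhesion molecule Icam1 (-1.33 ± 0.16), the prostaglandin synthase Ptgs2 (-1.30 ± 0.23) and Nfkb2 (-1.20 ± 0.17). The list median was -0.87 (camera adjusted p = 3.93e-13, and 0.0449 with an estimated correlation). Of 27 cytokines and chemokines, 5 were called lower and 0 higher, 6 and 1 when adjusted over the list alone and 8 and 0 with the block. They were Osm, Il6, Tnf, Ccl9 and Tnfsf14 (-1.09 ± 0.18), and the camera adjusted p was 5.99e-05, or 0.0449 with an estimated correlation and 0.0506 with the block and an estimated correlation. Among abundant chemokines, Ccl3 (12.69 and 12.70 in mCherry+ and mCherry-) and Cxcl2 (12.62 and 12.65) lay near the top of the scale. Their differences of -0.01 and -0.03 did not pass the test, and Ccl5 differed by 0.12 ± 0.30. Ccl4 (0.70 ± 0.22), Cxcl3 (-0.61 ± 0.26) and Ccl6 (-0.62 ± 0.41) moved the same way in 5 of 5 pairs without a call. In the limma fit with the block Cxcl3 and Ccl6 were called lower (adjusted p = 0.0322 and 0.041). Without the arrays numbered 1 the called members numbered 5 for NF-kB and 4 for cytokines. The higher Lcn2, Stfa2l1, Csf3r and Cd14 signal of mCherry- replicates 4 and 5 stands beside these lists too. The falls of both lists were not confined to those pairs. In pairs 1 to 3 the NF-kB list mean differed by -0.64, -0.67 and -0.89, and in pairs 4 and 5 by -0.93 and -0.71. For cytokines and chemokines these values were -0.63, -0.60 and -0.73, then -0.40 and -0.54.

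Single members of other lists changed without a call for the list. The granule ribonucleases Ear6 and Ear1 (-1.23 ± 0.23) were called lower among 14 measured eosinophil identity and granule genes, with 0 higher and the same 2 when adjusted over the list alone (camera adjusted p = 0.12), while the eosinophil receptors Siglecf and Ccr3 differed by 0.38 ± 0.27 and 0.12 ± 0.37 without a call. The death receptor Fas fell by 1.89 ± 0.28 among 22 survival and apoptosis genes. Icam1 fell among 25 chemokine receptor and integrin genes. The camera adjusted p of these lists was 0.721 and 0.329. In the lysosome list of 25 genes Cd68 rose (1.28 ± 0.23) and the protease Ctsd fell by 0.98 ± 0.16 (camera adjusted p = 0.12). Of 7 measured AHR target genes Cyp1b1 alone was called, and the AHR repressor Ahrr differed by 0.92 ± 0.24 (adjusted p = 0.124). Adjusted over the list alone 2 members were higher and 3 lower, the block added Nqo1 (-0.96) and Serpinb2 (-0.93) as lower, and the list's camera adjusted p was 0.845. TGF-beta response genes (19 measured, median -0.13) and glycolysis genes (25 measured, median -0.18) had 0 called members and passed camera at adjusted p = 0.0176 and 0.0248, but not with an estimated correlation (adjusted p = 0.18 and 0.404), and glycolysis not without the arrays numbered 1 (adjusted p = 0.249). Neither inhibitory receptors (17 measured, 2 lower), immunomodulatory genes (18, 0 called), MHC class II genes (11, 0 called), interferon-stimulated genes (13, 0 called), lipid mediator genes (16, 1 lower), oxidative phosphorylation genes (27, 0 called), proliferation genes (16, 0 called), immediate early genes (21, 1 higher) nor matrix and proteolysis genes (22, 1 lower) were called as lists, with camera adjusted p from 0.329 to 0.98. With the replicate block the members called higher and lower numbered 2 and 2 for inhibitory receptors, 2 and 0 for immunomodulatory genes, 1 and 5 for chemokine receptors and integrins, 1 and 3 for matrix and proteolysis genes, and 1 and 2 for lipid mediator genes. They numbered 2 and 1 for immediate early genes, 1 and 2 for lysosome genes, 0 and 2 for survival genes, 0 and 3 for eosinophil genes, and 0 and 1 each for proliferation, glycolysis and TGF-beta response genes.

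**Figure D2:**
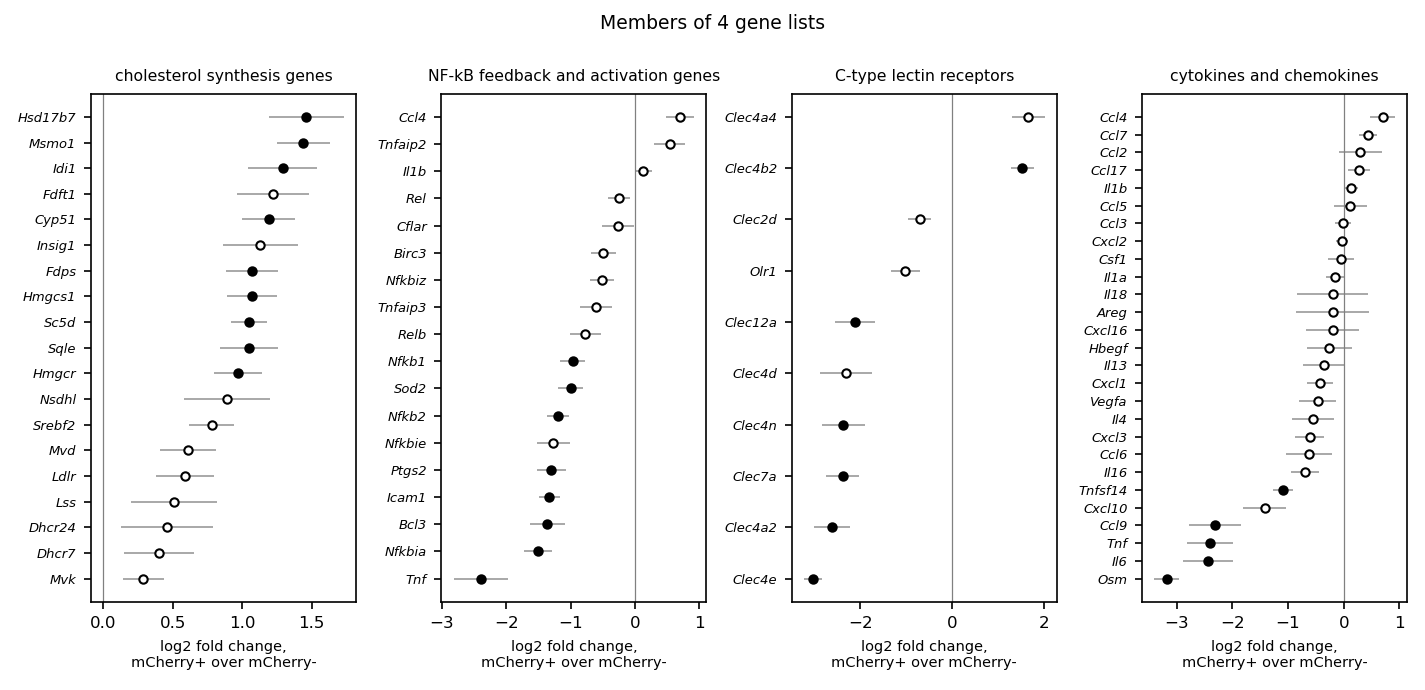
Log2 fold changes of mCherry+ over mCherry- eosinophils (horizontal axis) for each measured member of 4 gene lists, with bars of 1 SE and 5 arrays per group. Filled points mark genes with a limma adjusted p under 0.05; the cholesterol synthesis members all lie above 0, from 0.29 for Mvk to 1.46 for Hsd17b7.

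Among markers of other cell types, the neutrophil list was called, beside the erythroid and platelet list given above. The neutrophil list had 3 measured members, S100a8, S100a9 and Retnlg, and the first 2 were called lower in mCherry+ cells (camera adjusted p = 4.63e-06, 0.0286 with an estimated correlation, and 0.162 with the block and an estimated correlation). Retnlg was at 12.09 ± 0.29 and 12.18 ± 0.25. Members below the filter differed between arrays, with Lcn2 at 8.61 and 7.45 and Stfa2l1 at 7.74 and 6.01 on mCherry- replicates 4 and 5, against at most 5.19 and 3.05 on the other 8 arrays. The 8 macrophage and monocyte markers had 0 called members, a median of 0.26 and a mean of -0.10 (camera adjusted p = 0.972). Adjusted over the list alone 2 were lower, Cd14 at -2.18 ± 0.68 (adjusted p over all genes 0.238) and Csf1r at -0.40 ± 0.13, each in 5 of 5 pairs. Epithelial transcripts were abundant in both groups, with Apoa1 at 11.94 ± 1.21 and 11.91 ± 1.44 and Krt8 at 11.53 ± 0.79 and 11.61 ± 0.96, and the median over 20 epithelial markers was -0.03 (camera adjusted p = 0.843). On the arrays numbered 1 they were lower, with Fabp1 at 8.15 and 7.43 against 10.99 to 11.81 elsewhere. Dendritic cell (5 measured), B and plasma cell (4), T and NK cell (10) and stromal markers (9) had 0 called members and were not called as lists (camera adjusted p = 0.545, 0.721, 0.845 and 0.329). Stromal markers had 1 member called higher and passed camera with the replicate block (adjusted p = 0.0418), but not with the block and an estimated correlation (adjusted p = 0.408).

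The WT Clec4a4+ and WT Clec4a4- arrays ask the same question in mice without the reporter, with 1 array per group, so that no difference has a replicate check. Clec4a4 was at 9.14 and 5.56, a log2 difference of 3.58. Other genes far higher on the Clec4a4+ array were the apolipoprotein L gene Apol7c (5.23), Dpep2 (4.78), the cadherin Cdh17 (3.61), the lectin Cd209a (3.54), haemoglobin Hbb-bt (3.46), Cd22 (3.24), Ly86 (3.01), the neuromedin receptor Nmur1 (3.01) and the MHC class II chain H2-Ab1 (2.67). With probe sets averaged Dpep2 differed by 3.63 and Hbb-bt by 1.83. Far higher on the Clec4a4- array were the resistin-like gene Retnla (-6.44), the gastrokine Gkn2 (-5.34) and 7 alpha-defensins, antimicrobial peptides of Paneth cells, from Defa17 (-6.54) and Defa38 (-5.45) to Defa24 (-3.71), and the lectin Clec12a (-3.81). Where 1 array of the pair lay below its median of 4.73 or 4.75 these sizes are not exact. This held for Apol7c (4.13), Cd209a (4.10), Hbb-bt (2.71) and Ly86 (4.52) on the Clec4a4- array and for Retnla (4.71), Gkn2 (4.45), Defa24 (4.50) and Defa33 (4.31) on the Clec4a4+ array. Of 24903 genes 13484 lay above the median on the higher array, and 161 of these were at least 2-fold higher and 258 at least 2-fold lower on the Clec4a4+ array, with an SD of 0.44 over all detected differences.

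Grouped by the fixed lists, MHC class II genes had the highest median difference among the pathway lists of this pair, with 6 of 12 detected members at least 2-fold higher and 0 lower on the Clec4a4+ array, and a median of 0.96. Cd74 and H2-Eb1 were at 2.18 and 2.29, and 95% of matched random lists had medians between -0.23 and 0.17. On the reporter arrays the same list had a median of -0.03. Cholesterol synthesis genes had 8 of 18 members at least 2-fold higher and a median of 0.70 (random lists -0.19 to 0.13), with Fdps at 1.64, Msmo1 at 1.52 and Fdft1 at 1.51. C-type lectin receptors had 3 members at least 2-fold higher, among them Clec4b1 (2.36), and 6 lower, with a median of -0.78 (random lists -0.22 to 0.19), where Clec4b1 lay at 3.16 on the Clec4a4- array, and NF-kB genes a median of -0.67 (-0.22 to 0.10). The eosinophil list had a median of -0.37 (-0.21 to 0.14), with the alarmin receptor Il1rl1 at -1.80 (4.07 on the Clec4a4+ array) and the granule protein Prg2 at -1.20, and AHR targets of -0.12 (-0.26 to 0.22), with Ahrr at 2.16. Markers of other cells differed too, with medians of 1.40 for 5 erythroid and platelet markers, 0.47 for 12 T and NK cell markers (Cd3g 1.32) and -0.48 for 16 epithelial markers (Lyz1, a Paneth cell lysozyme, -2.69). Medians below the range of random lists were also those of chemokine receptors and integrins (-0.43), matrix and proteolysis genes (-0.34), stromal markers (-0.34), glycolysis genes (-0.31) and TGF-beta response genes (-0.31). The other tested lists, neutrophil (-0.21), macrophage (0.16), dendritic cell (0.03) and B cell markers (0.11) among them, lay inside it. S100a8 and S100a9 differed by -3.43 and -1.30, with S100a8 at 3.27 on the Clec4a4+ array, below its median, and with Lcn2 at 5.11 and 5.47 and Stfa2l1 at 2.40 and 2.67.

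The genes defined on the reporter arrays differed in the same direction between these WT arrays. All 38 genes called at least 2-fold higher in mCherry+ cells had positive differences on the WT pair, 19 of them at least 2-fold, with a median of 0.99 where 95% of matched random lists lay between -0.13 and 0.08. Of the 50 genes called at least 2-fold lower, 49 were on both array designs and 48 had negative differences, 30 of them at least 2-fold, with a median of -1.26 (random lists -0.13 to 0.05). The exception was Marcksl1, at 0.00. Sizes varied, with Fcrls at 2.00 (2.36 on the reporter arrays), Acod1 at -2.30 (-2.77), Clec4e at -2.14 (-3.03), Cyp1b1 at 0.22 (2.81), Egr2 at 0.24 (1.66) and Ear6 at -0.28 (-2.87). Fcrls lay at 4.41 on the Clec4a4- array, and Cyp1b1 and Ear6 were dim on all 3 of these arrays, with Cyp1b1 at 4.92 and 4.70.

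The third comparison, of the array labelled Ahr KO Clec4a4- with the WT Clec4a4- array, asks which genes depend on AHR. Ahr transcript was not lower on the array labelled Ahr KO by its brighter probe set, and the mean over its probe sets differed by -0.18. The brighter of its 2 probe sets read 11.12, against 11.08 on the WT Clec4a4- and 11.11 on the WT Clec4a4+ array, and the other 7.43 against 7.83 and 7.60. The labels do not say which part of the gene was deleted, so probes outside it check nothing, and the label of this array rests on the submitters. AHR target genes were lower on it. All 6 detected members had negative differences, with the ADP-ribosyltransferase Tiparp at -3.56, the quinone reductase Nqo1 at -2.94 and the serpin Serpinb2 at -2.26, and the median was -1.48, where 95% of matched random lists lay between -0.31 and 0.27. With probe sets averaged Tiparp differed by -2.41. Nqo1 lay at 4.25 on this array, below its median of 4.73, so that its size is not exact. Clec4a4 was at 3.93 on it and 5.56 on the WT Clec4a4- array (-1.63), the former below the array median.

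Other large differences on the array labelled Ahr KO were the chemokine Cxcl3 (-3.60), Ptgs2 (-2.53), Retnla (-2.84) and 8 alpha-defensins (Defa38 -5.12, Defa17 -4.51), which were brighter on the WT Clec4a4- array (Defa17 at 11.54) than on the WT Clec4a4+ array (5.00) and this one (7.04). In the other direction were Cd22 (4.23), Cdh17 (3.72), Hbb-bt (3.65), Klra17 (2.90), the long noncoding RNA Lncpint (2.87), Tgfb2 (2.54) and Cd7 (2.04). The shared cytokine receptor chains Csf2rb and Csf2rb2 differed by -1.68 and -1.81 and the chemokine receptor Ccr1 by -1.70, and the survival gene Bcl2 by 1.61. With probe sets averaged Bcl2 differed by 0.66 and Hbb-bt by 1.81. Hbb-bt (2.71), Klra17 (4.11), Lncpint (4.72) and Tgfb2 (4.70) lay below the median of 4.73 on the WT Clec4a4- array, so that their sizes are not exact. In all 149 genes were at least 2-fold higher and 193 at least 2-fold lower on the array labelled Ahr KO, out of 13478 detected. C-type lectin receptors had a median of -0.92 (random lists -0.20 to 0.19), cholesterol synthesis genes 0.33 (-0.14 to 0.16), NF-kB genes -0.31 (-0.19 to 0.13) and MHC class II genes -0.33 (-0.18 to 0.20). Glycolysis genes had a median of -0.16 (-0.14 to 0.12), and the medians of the other tested lists besides AHR targets lay inside the range of random lists.

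The question of whether genes that mark Clec4a4+ cells differ with the Ahr label was put to the reporter-defined lists. Of the 38 genes higher in mCherry+ cells, 28 had positive and 10 negative differences between the array labelled Ahr KO and the WT Clec4a4- array, with a median of 0.37 (random lists -0.09 to 0.10). Those at least 2-fold higher were Cd22 (4.23), F2rl3 (1.58), Clec4b2 (1.57), Cyp51 (1.56) and Slco4a1 (1.14), while Dpep2 (-0.31), Fcrls (-0.01) and Ly86 (0.36) did not differ 2-fold from the WT Clec4a4- array and lay below the WT Clec4a4+ array (-5.09, -2.01 and -2.65). Dpep2 (4.64) and Fcrls (4.41) were below the median of 4.73 on the array labelled Ahr KO, so that these sizes are not exact. Of the 49 matched genes lower in mCherry+ cells, 43 had negative differences, 14 of them at least 2-fold, with a median of -0.64 (random lists -0.10 to 0.09). Clec4e (-1.64), Clec7a (-1.58) and Clec4a2 (-1.54) were among these, whereas S100a9 (0.10), Il6 (0.58) and Rassf4 (-0.14) were not. As each group has 1 array, these values describe the arrays, and a difference between mice of the same genotype is not excluded by them.

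**Figure D3:**
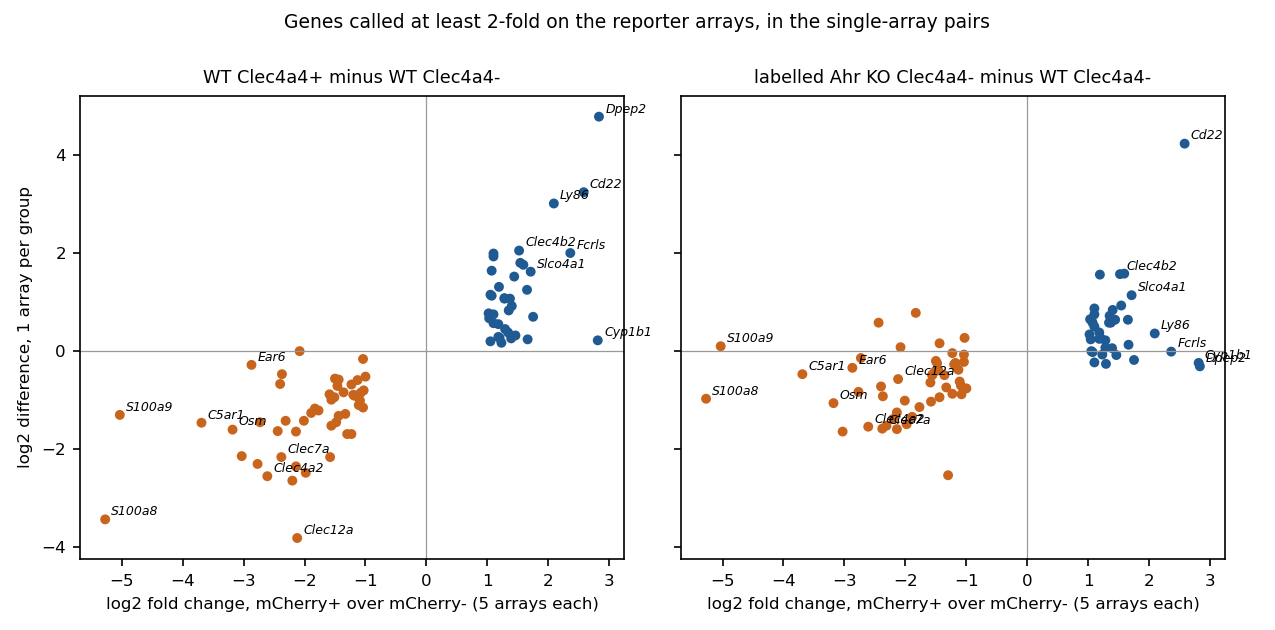
Log2 fold change of mCherry+ over mCherry- eosinophils (horizontal axis, 5 arrays per group) against the log2 difference in each single-array pair (vertical axis) for 87 genes called at least 2-fold on the reporter arrays. Blue points were higher and orange points lower in mCherry+ cells; medians were 0.99 and -1.26 in the WT pair and 0.37 and -0.64 in the pair with the array labelled Ahr KO.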

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

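The tests of neutrophils in separate pairs, of B cells, of the WT Clec4a4- array and both of remaining Clec4a4+ cells were chosen after the results were seen. Of 138 groups of 5 values (named genes and list means on the reporter arrays), 10 had 1 array far from the others, where chance gives 6.9, and 8 of the 10 were arrays numbered 4. On mCherry+ replicate 4, Ahr (10.32, others at least 11.22), Dpep2 (9.12, others at least 9.99) and Cyp1b1 (8.12, others at least 9.11) were low and the proliferation list mean (6.92, others at most 6.52) was high. On mCherry- replicate 4, Clec4a4 (6.42, others at least 7.70) and Ctsd (9.19, others at least 9.61) were low, and Cd68 (8.21, others at most 7.48) and the stromal list mean (8.23, others at most 7.21) were high. Cyp51 was high on mCherry+ replicate 5 (10.15, others at most 9.55), and the epithelial list mean was low on mCherry- replicate 1 (8.17, others at least 10.20).

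For 3 lists the mean difference was positive in 5 of 5 reporter pairs (mCherry+ minus mCherry-) and negative on the WT pair (Clec4a4+ minus Clec4a4-). This contrast was not tested and rests on 1 WT array per group. The 3 lists were immunomodulatory genes (0.02 to 0.14, and -0.37), lysosome genes (0.02 to 0.27, and -0.03) and stromal markers (0.01 to 0.57, and -0.23). The WT values cover other members too, Retnla (-6.44) among the immunomodulatory genes, and over the members measured on the reporter arrays they were -0.12, -0.03 and -0.18. Among 4646 tested probe sets without a gene name, 2 were called between mCherry+ and mCherry- eosinophils (limma adjusted p = 0.0325 each), probe set 10338961 at 6.97 ± 0.54 and 3.91 ± 0.73 and probe set 10527934 at 7.62 ± 0.30 and 6.12 ± 0.26 (log2 values, SD, 5 arrays per group), and 321 had an unadjusted p under 0.05.

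S100a8, S100a9 and other myeloid genes were far lower in mCherry+ eosinophils. A large share of macrophages in the mCherry- sort is argued against by the median of 0.26 over the 8 measured macrophage and monocyte markers. Medians per pair ran from -0.26 to 0.53, and Lyz2 was at 0.34. The pooled median cannot decide on monocytes, since Cd14 (-2.18), Csf1r (-0.40) and Ly6c2 (-0.12) had negative differences while the other members had positive ones. A small share of macrophages is not excluded either, since Cd14 and Csf1r were lower in 5 of 5 pairs. Lyz2 was also well expressed in both groups (8.95 and 8.61 in mCherry+ and mCherry-) and could hide such a share. Over all pairs, neutrophils cannot be told apart from a difference between the subsets, because the 1 other neutrophil marker above the filter, Retnlg (-0.10), was near the top of the scale in both groups and would hide a small share. In pairs 4 and 5, Lcn2, Stfa2l1 and Mmp8 were higher on the mCherry- arrays by a median of 3.17, which decides nothing, since the genes and pairs were picked for that rise. On mCherry- replicates 1 to 3 they lay at a median of -1.59 from the level that their ratio to S100a8 on mCherry- replicate 4 needs (Lcn2 -1.49 to -1.59, Stfa2l1 -2.28 to -3.40, Mmp8 -0.14 to -0.75), but the needed levels of Stfa2l1 and Mmp8 are themselves under 6, so neutrophils stay open there too, as does, untested, a higher S100a8 and S100a9 level of the Clec4a4- subset itself.

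MHC class II genes were higher on the WT Clec4a4+ than on the WT Clec4a4- array. The list's median on the reporter arrays was -0.03, with pair medians from -0.37 to 0.15, so no such rise was seen there. These values cannot decide whether the rise is shared, since class II transcripts of other cells could hide a difference between the subsets there. Epithelial transcripts were abundant on the reporter arrays, and the list's mean varied with the replicate number. It was 6.87 and 7.01 in mCherry+ and mCherry- replicate 1, and 7.86 and 7.71 in replicate 4. B cells are argued against by a median of 0.11 over 9 B and plasma cell markers, with Cd79a at -0.27. Dendritic cells cannot be told apart from a property of this sort, since 5 of the 8 detected markers other than Cd209a were under 6 on both arrays and most of them mark the Xcr1-expressing subset, so that their median of -0.04 decides little, while Cd209a, which marks another subset, was higher by 3.54. The reporter and the WT sorts differ in how Clec4a4 was detected and in array design, which may also play a part and was not tested.

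A set of 50 genes, Cd22 and Cdh17 among them, was at least 2-fold higher on both the WT Clec4a4+ array and the array labelled Ahr KO than on the WT Clec4a4- array, which both differences share. Of this set, the 35 genes measured on the reporter arrays had a median log2 fold change of 0.72 there, 30 of them positive and 5 called. Medians of 95% of matched random lists lay between -0.09 and 0.10. The set was picked for being higher in the WT pair, whose differences went with the reporter fold changes over 11399 genes (correlation 0.45). A positive median was therefore likely beforehand, and the random lists were matched on mean level only. These values cannot decide whether an oddity of the WT Clec4a4- array made the array labelled Ahr KO look alike. Left-over cells with the profile of the WT Clec4a4+ array are argued against, since 14 of 22 genes at least 4-fold higher on that array lay 1 or more below the level they would need (Apol7c -5.78, Cd209a -3.63, Nmur1 -3.29) and Cd22 lay 0.99 above that array. Cells of the Clec4a4+ type whose genes had changed with the genotype cannot be told apart from other differences between the genotypes, because the sort was on Clec4a4 (-1.63) and cells that had lost Clec4a4 and Dpep2 (-0.31) would pass it. No biological explanation was tested, and each group has 1 array.

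Among drawn splits that ignore the numbered pairs, the real split gave the highest counts of the reporter comparison. Such splits cannot exclude chance as the source of these counts, since the arrays were taken as paired. Of 100 splits of the 10 arrays into groups of 5, 1, the real one, gave as many as 119 genes, and the highest other count was 108. Of the same 100 splits, 1 gave as many as 88 genes changed at least 2-fold, and the highest other count was 56. The split with 108 genes exchanged mCherry- replicate 1 and mCherry+ replicate 4, so that it joined the array numbered 1 to most mCherry+ arrays, along the first principal component. Splits that part all 5 numbered pairs, as the real one does, number 16, too few for a share under 0.05. Of these 14 were among the drawn splits, with 119 genes for the real one and at most 0 for the others, and with the replicate block the 16 gave 403 and at most 0.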

How the results depend on the processing

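Leaving out both arrays numbered 1 or 4 was chosen after the data were seen. For the 41 named genes of the reporter comparison, 0 of 932 values under the alternatives changed sign, 814 kept their side of the threshold, 107 lost and 11 gained a call. Of 984 values of named genes in the single-array pairs, 9 moved by more than the SD of all differences in their pair, all with probe sets averaged (Dpep2 from 4.78 to 3.63 in the WT pair, and Hbb-bt from 3.65 to 1.81 in the other). Differences near 0 changed sign for Ahr with probe sets averaged (0.03 to -0.10 in the WT pair and 0.04 to -0.18 in the pair with the array labelled Ahr KO), for Csf1 renormalized (-0.08 to 0.01) and for Ctsc centred (0.01 to -0.01). The count of genes differing between mCherry+ and mCherry- eosinophils, 119, was 403 with the replicate block, 207 with array quality weights, 27 at an adjusted p under 0.01, 213 at 0.10, 52 without the arrays numbered 1 and 156 without those numbered 4. With the block, the 403 became 166 without the arrays numbered 1 and 302 without those numbered 4. Without single arrays it ran from 45 (without mCherry+ replicate 3) to 149 (without mCherry+ replicate 4), with fewer arrays in each fit. The count of genes differing at least 2-fold between mCherry+ and mCherry- eosinophils, 88, was 155 with the replicate block, 140 with array quality weights, 44 without the arrays numbered 1 and 120 without those numbered 4 (with the block 106 and 176), and ran from 38 (without mCherry+ replicate 5) to 112 (without mCherry+ replicate 4). The 8 called lists became 5 with an estimated correlation. The filter, renormalization, centring, the prior of limma, and the probe set rule kept both counts within 1.5 times, from 86 to 137 and from 66 to 102. The count of genes differing at least 2-fold between the WT Clec4a4+ and WT Clec4a4- arrays, 419, was 1423 at 1.5-fold and 116 at 3-fold. The count of genes differing at least 2-fold between the Ahr KO Clec4a4- and WT Clec4a4- arrays, 342, was 1301 and 89, as the size rule itself makes it. The median of the higher reporter-defined genes in the WT pair, 0.99, was 0.75 with lists of any size and 0.83 with lists from the fit with the replicate block, and that of the lower genes, -1.26, was -1.11 with lists of any size. In the pair with the array labelled Ahr KO these medians, 0.37 and -0.64, ran from 0.35 to 0.44 and from -0.70 to -0.57. The form of the deposited table held equal values and so tested nothing. Where no value shows it, the cause was not tested. Dim genes near the array median (5.18 to 5.27) have compressed differences in RMA values as a property of the method, which was not measured here.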

Other observations

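The deposited reporter arrays also differ in genes of the sex chromosomes, of which Ddx3y was among the tested genes and Xist was removed by the filter. Both arrays numbered 1 had Xist at 9.90 and 10.36 and Ddx3y at 3.62 and 3.56, while the other 8 had Xist between 3.56 and 3.93 and Ddx3y between 8.19 and 9.44. The 3 single arrays all had Xist signal, at 10.78, 10.91 and 10.69, with Ddx3y at 3.62, 3.59 and 3.98.

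Fabp1, an epithelial fatty acid-binding protein gene, was between 7.43 and 11.81 on the reporter arrays and at 5.54, 4.78 and 5.18 on the single arrays, whose design and normalization differ. The haemoglobin gene Hbb-bt was higher in mCherry+ cells in 5 of 5 pairs (1.60 ± 0.66, limma adjusted p = 0.442) and was at 6.17, 2.71 and 6.36 on the WT Clec4a4+, WT Clec4a4- and Ahr KO-labelled arrays.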
